A study of Drosophila melanogaster with 18 samples.

How the data were processed

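Whole heads of Drosophila melanogaster of the wild-type strain Canton-S were compared on one-colour Affymetrix oligonucleotide arrays, per the labels. Each of the 18 samples held about 60 heads of flies aged 2 to 5 days, and biotin-labelled cRNA was made from 6 µg of total RNA. The sample titles gave 3 groups of 6 biological replicates each. Naive flies received 50 min of humidified air. Single-exposure flies received the air period and 1 exposure of 40 min to 50% ethanol vapor. Five-exposure flies received the air period and 5 such exposures. The sex of the flies, the interval between exposures and the time of day at collection are not given in the sources used here. No air-only group matched in duration to the 1 or the 5 exposures was analysed here.

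The deposited table held 1 intensity per probe set and array, on a linear scale, already summarised and normalized between arrays by the authors. The summarising and normalizing software is not given in the sources used here, and the table carried no detection calls. It held 14010 probe sets, of which 44 were controls. Gene symbols came from the platform annotation, updated through the gene identifiers of a current gene table. A single symbol was found for 12444 probe sets, several for 327 and none for 1239, and no gene was named from a probe set with several symbols. The 18 array medians lay between 125.4 and 129.3 and the maxima between 10996 and 12033, so arrays differed little in overall scale.

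Values below the pooled 20th percentile (57.8) were set to that floor and log2 was taken. Control probe sets and the lowest 1/3 by mean log2 value (below 6.42, an intensity of 85.8) were left out, which left 9317 probe sets. Of these, 8303 carried a single gene symbol, for 7466 genes, and 1014 carried several or none. Of the 9317, 12 probe sets had any array at the floor, and their fitted folds depend on the floor. One linear model with the 3 groups was fitted to all 18 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, equal weights, no block), so that the comparisons share 1 estimate of the spread on 15 residual degrees of freedom. Calls were made at a Benjamini-Hochberg adjusted p under 0.05, two-sided, over all probe sets of a comparison. Every p-value from this fit measures the spread between samples that the labels name as biological replicates. Folds are given with 95% confidence intervals from the model, intensities as mean ± SD of 6 arrays. The number of arrays limits the precision.

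Before the data were examined, 40 lists of genes were fixed, of pathways and of markers of tissues, cell types and sex that heads could carry, together with the alternatives below. They held 1223 names, of which 933 matched a probe set. Each gene was represented by its probe set with the highest mean over all arrays, and probe sets that disagreed are mentioned where the gene is named. The 37 lists with at least 5 tested members were tested with camera, which asks whether the members shifted relative to all other genes, at a preset inter-gene correlation of 0.01. Adjustment was over the lists of a comparison. Camera with an estimated correlation and fry were run beside it.

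Genes named in the text followed a rule fixed at the same time. It took the 10 highest and 10 lowest folds among called genes of each comparison, up to 4 members with the smallest p of each called list and up to 2 of each other list, a fixed panel of ethanol, clock, stress, immune and housekeeping genes, and the 3 genes with the smallest p called in the same direction in both comparisons with naive flies. Of the panel, Adh, Aldh, homer, Hr38, Hsp83, AttA, Thor and Act5C had no tested probe set of their own and were not analysed here.

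The procedure was tested on simulated data for the comparison of single exposure with naive over 9317 probe sets. It recovered 82% of 50 probe sets changed 1.2-fold, 98% of 50 changed 1.5-fold and 100% of those changed 2-fold or 3-fold, with 5 false calls. The simulated noise was normal and independent between probe sets and arrays, so these rates need not hold for the real arrays. Alternatives were quantile normalization, median centring, no filter on low values, a stricter filter at the median, a pseudocount in place of the floor, a floor at the 5th percentile (24.9), a trended and robust prior, only the 2 groups compared, array weights, a replicate block, and each array left out in turn. One further alternative, without the least correlated array of each group, was chosen after seeing the data. No arrays were duplicates: the smallest SD of log2 differences between any 2 arrays was 0.11 and the largest 0.265. Array numbers in the titles run consecutively by group, so any effect of array order or batch and the group cannot be told apart. Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were used for tables and plots.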

Results

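Transcript levels in whole fly heads were measured after air alone, after 1 exposure to ethanol vapor and after 5 exposures, with 6 arrays per group. The series concerns ethanol tolerance that builds up fast, after 1 exposure, or chronically, after repeated exposures. Of the variance of the 9317 tested probe sets, the first principal component held 23.1%, the second 16.9% and the third 14.4%. The 6 five-exposure arrays had values from 4.29 to 9.41 on the first component and the single-exposure arrays from -10.29 to -3.25. Naive arrays lay between -8.39 and 2.86. On the second component naive arrays lay from 0.09 to 13.24, single-exposure arrays from -7.37 to -3.61 and five-exposure arrays from -1.56 to 2.49. Naive replicate 5 had the lowest mean correlation with its own group (0.988), and it lay above the other 17 arrays on each of the 4 hybridization spikes, as at log2 10.23 against at most 9.76 for BioC and 13.05 against at most 12.84 for CreX.

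The first comparison asks which transcripts differed between heads of flies given 1 ethanol exposure and naive heads. After 1 exposure, 30 of 114 tested glutathione S-transferase, cytochrome P450, lipid synthesis and storage, and chaperone genes were higher, and the genes called lower included the fat body transcript fit and the gene for the hormone limostatin. The 4 lists of these 114 genes passed camera at its preset correlation but not with an estimated correlation (adjusted p = 0.176 to 0.430). The glutathione S-transferase GstE7 rose from an intensity of 49.6 ± 7.7 to 346 ± 61.8, and the lipid droplet coat protein Lsd-1 from 636 ± 84.4 to 2493 ± 275 (SD, n = 6 each). The fitted fold of GstE7 was 5.85, a size that depends on how low values are handled, because 5 of the 6 naive arrays lay at the floor: it was 3.73 with a pseudocount in place of the floor and 6.96 with a lower floor. That of Lsd-1 was 3.93 (95% interval 3.41 to 4.54). In limma, 412 of 9317 probe sets passed the threshold, 239 higher and 173 lower. The excess of higher calls was not kept under median centring (206 higher and 201 lower), quantile normalization (223 and 213) or without naive replicate 5 (210 and 213). Most changes were small: 44 rose and 12 fell by over 1.5-fold, and the median change of called probe sets was 1.22-fold. Groups did not overlap for 280 probe sets (3.01%, where chance gives 0.216%).

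Among the 10 highest folds after 1 exposure were also GstE3 (2.86-fold, 2.40 to 3.40), CG6908 (2.71-fold, 2.48 to 2.96), CG5966 (2.69-fold, with 4 naive arrays at the floor, 2.25-fold with a pseudocount and 3.99-fold with a lower floor) and Pepck1, which encodes phosphoenolpyruvate carboxykinase of gluconeogenesis (2.35-fold, 1.79 to 3.08). They were joined by the juvenile hormone epoxide hydrolase gene Jheh2 (2.20-fold, 1.97 to 2.46), the UDP-glycosyltransferase gene Ugt37A3 (2.19-fold, 1.69 to 2.82), Nmdmc, which encodes a mitochondrial folate enzyme (2.17-fold, 1.89 to 2.50), and CG16926 (2.05-fold, 1.85 to 2.27). The adjusted p of these 10 lay between 4.15e-15 and 0.000313. The lowest fold was that of fit, at 0.398 (0.319 to 0.498), from an intensity of 2544 ± 368 to 1027 ± 251 (n = 6 each, limma adjusted p = 6.6e-06). CG10621 fell to 0.401-fold, phu to 0.439-fold, Lst, the limostatin gene, to 0.527-fold and CG5172 to 0.533-fold. The peptidoglycan recognition gene PGRP-SB1 fell to 0.541-fold (0.492 to 0.596), followed by Srg1 (0.597-fold), ana (0.624-fold), CG8665 (0.627-fold) and CG15096 (0.633-fold).

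Grouped by the fixed lists, 9 of 28 tested glutathione S-transferases rose and 1 fell (10 and 3 adjusted over the list alone), with GstD1 at 1.51-fold and GstE1 at 1.34-fold. The list passed camera with an adjusted p of 0.000121, and with an estimated correlation the adjusted p = 0.176. Of 56 cytochrome P450 genes, 13 rose and 2 fell (14 and 4 adjusted over the list alone), among them Cyp6d5 (1.95-fold, 1.72 to 2.22), Cyp6a2 (1.88-fold, 1.72 to 2.05), Cyp6w1 (1.82-fold, 1.62 to 2.04) and Cyp4p1 (1.60-fold, 1.46 to 1.76). The list's adjusted p was 0.00218, with an estimated correlation the adjusted p = 0.291, and without a filter on low values it was 0.129, which ends the call. In fatty acid synthesis and lipid storage, 4 of 18 members rose and 1 fell (6 and 2 adjusted over the list alone). Besides Lsd-1 these were ATPCL, which makes cytosolic acetyl-CoA from citrate (1.98-fold, 1.82 to 2.16), the acyltransferase gene Agpat2 (1.90-fold, 1.75 to 2.06) and the fatty acid synthase gene FASN1 (1.57-fold, 1.38 to 1.79). The list had an adjusted p of 7.83e-05, and adjusted p = 0.291 with an estimated correlation. Men, the gene of an NADP-dependent malic enzyme, rose 1.95-fold (1.78 to 2.14), and the acetyl-CoA synthetase gene AcCoAS 1.58-fold (1.42 to 1.76), although their list, alcohol and aldehyde metabolism, did not pass (adjusted p = 0.896, 2 higher and 2 lower of 14).

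Of 12 heat shock and cytosolic chaperone genes, 4 rose and none fell (6 higher and 1 lower adjusted over the list alone; list adjusted p = 0.0131, adjusted p = 0.430 with an estimated correlation). They were Hsp26 (1.61-fold, 1.24 to 2.08), DnaJ-1 (log2 fold change 0.59), Stip1 (1.35-fold, 1.15 to 1.58) and Hsc70-4 (1.28-fold, 1.18 to 1.39). Single-exposure replicate 3 stood high for Hsp26, Stip1 and Hsc70-4, and without it the log2 fold change of Hsp26 moved from 0.69 to 0.44, still called. In glycolysis and trehalose metabolism 3 of 21 members rose, Pepck1, the trehalose synthesis gene Tps1 (1.31-fold) and Pgi (1.17-fold), while the hexokinase gene Hex-A fell to 0.842-fold (6 higher and 1 lower adjusted over the list alone, list adjusted p = 0.0154, adjusted p = 0.430 with an estimated correlation). The call of this list was lost without naive replicate 4 (adjusted p = 0.0905), naive replicate 6 (0.0532), single-exposure replicate 1 (0.0988) or single-exposure replicate 3 (0.0725). Oxidative phosphorylation moved down as a list by a small amount. Of 47 members 3 had a fold above 1, the median log2 fold change was -0.09, and 2 members fell and none rose (6 lower adjusted over the list alone), ND-18 (0.870-fold) and ND-B14 (0.904-fold). The list adjusted p was 1.73e-11, with adjusted p = 0.395 with an estimated correlation.

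In neurotransmitter synthesis and transport, 4 of 17 genes fell and none rose: ple, the tyrosine hydroxylase gene of dopamine synthesis (0.733-fold, 0.650 to 0.827), speck (0.741-fold), Pu, the GTP cyclohydrolase gene (0.763-fold), and the GABA transporter gene Gat (0.789-fold). Adjusted over the list alone 4 fell. The list adjusted p was 0.00315, and adjusted p = 0.176 with an estimated correlation. Activity-regulated genes also moved down (3 of 12 lower, none higher, 4 lower adjusted over the list alone, list adjusted p = 0.00315, adjusted p = 0.176 with an estimated correlation), with the transcription factor gene sr at 0.684-fold (0.591 to 0.792), CG13868 at 0.701-fold and CG14186 at 0.886-fold. Antimicrobial and immune recognition genes had PGRP-SB1 and Tl (0.889-fold) lower and none higher of 20 (2 lower adjusted over the list alone, list adjusted p = 0.0154, adjusted p = 0.350 with an estimated correlation), a call lost without naive replicate 6 (0.0637) or single-exposure replicate 2 (0.0559) and without a filter on low values (0.0986). Muscle markers moved down as a list (adjusted p = 0.0154) with 0 of 20 members called by limma (4 at an unadjusted p under 0.05), but not with an estimated correlation (adjusted p = 0.662) or without naive replicate 5 (0.0990).

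The clock list did not pass (adjusted p = 0.576), with 3 of 16 members higher and 2 lower. The deubiquitinase gene Usp8 rose 1.84-fold, tim 1.29-fold (1.14 to 1.47) on the chosen probe set, with a second probe set not called (adjusted p = 0.255), and vri 1.25-fold (1.15 to 1.36). Clk fell to 0.755-fold (0.690 to 0.826) and cwo on the chosen probe set only, at -0.33 log2 (adjusted p = 0.00673), with its second probe set at -0.16 (adjusted p = 0.0733). The fold of per was 1.11 (adjusted p = 0.0897). Of genes with reported roles in fly ethanol behaviour, 24 were tested, Men was higher, Egfr (0.774-fold, with a second probe set not called, adjusted p = 0.0988) and chico (0.906-fold) were lower, and hang (0.997-fold) and slo (0.926-fold) were not called. The remaining lists did not pass camera at its preset correlation, at adjusted p from 0.0524 (glia markers) to 0.921. They covered markers of neurons, photoreceptors, fat body, haemocytes, cuticle, gut, testis, ovary and female heads, the ER stress and oxidative stress responses, fatty acid oxidation, maltases, UDP-glycosyltransferases, insulin and starvation, histone acetylation, ion channels, synaptic vesicles, learning, neuropeptides, odorant binding, ribosomal proteins and the proteasome. Too few members were tested for accessory gland markers (1), male-biased genes (3) and the Turandot list (3). The gene fit, the lowest fold of this comparison, is also in the list of 5 female-biased head genes, as the 1 member called. The yolk protein gene Yp1 of that list was at 1.01-fold, near the top of the intensity scale, and the sex of the flies is not given in the sources used here.

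Of the genes named, some calls were lost when 1 array was left out, for Tl without any of 14 arrays (adjusted p up to 0.135), chico 10 (0.0968), ND-B14 8 (0.0848), Pgi 5 (0.0711), Egfr 5 (0.0681), ND-18 4 (0.0676), Hsp26 4 (0.0620), Hex-A 2 (0.0642) and Stip1 1 (0.0516). Without a filter on low values the calls of Hsp26 (0.109), Egfr (0.0860), Stip1 (0.0845), Tl (0.0742), tim (0.0644), Pgi (0.0600) and Hex-A (0.0598) were lost. With only the 2 groups compared they were lost for ND-B14 (0.0920), Hsp26 (0.0863), Pgi (0.0688), Stip1 and ND-18 (0.0654 each), Tl (0.0624) and chico (0.0590). The call of ND-B14 was also lost with array weights (0.0538) and without the least correlated arrays (0.136), that of ND-18 in the latter (0.119), and that of Hsp26 with a trended and robust prior (0.0584). The number of lists called here, 10, was reached by 11 of 100 splits of the 12 arrays, the real one included, so the list calls stand on weaker ground than the gene calls. The 3' to 5' log2 ratio of the 18S rRNA control probe sets was -2.92 ± 0.44 in naive and -1.99 ± 0.23 in single-exposure arrays (n = 6 each, exact permutation p = 0.00216, adjusted p = 0.0518 over 24 comparisons). The 2 groups did not overlap, with naive arrays at most at -2.385 and single-exposure arrays at least at -2.346. This p is the smallest that 6 against 6 arrays can give, so over 24 comparisons 1 fully separated ratio alone cannot pass 0.05.

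**Figure D1:**
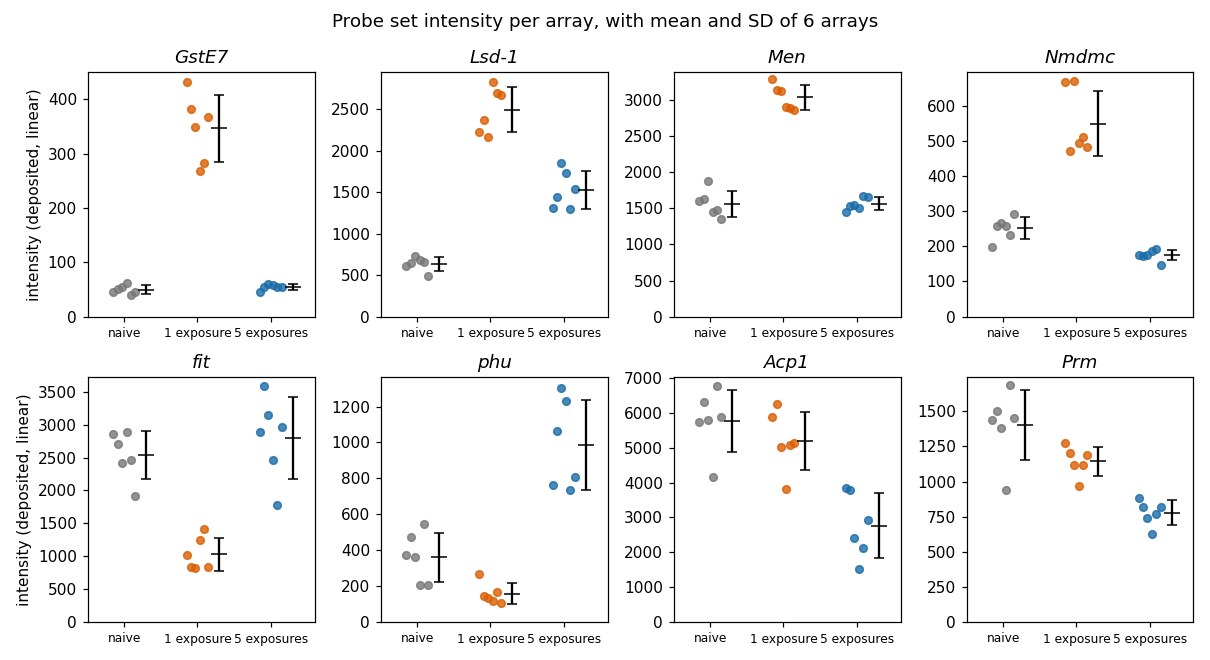
Deposited intensity (linear, vertical axis from 0) of 8 probe sets in naive, single-exposure and five-exposure heads, one point per array with mean and SD of 6 arrays beside. GstE7, Lsd-1, Men and Nmdmc were highest after 1 exposure, fit was lowest after 1 exposure, phu was highest after 5 exposures, and Acp1 and Prm were lowest after 5 exposures, where the Acp1 mean was 2768.

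The second comparison asks which transcripts differed between heads after 5 exposures and naive heads. Of 20 muscle markers 13 were lower, of 46 cuticle protein genes 11 were lower, and of 10 fatty acid oxidation genes 6 were higher, as were the lipid droplet genes Lsd-1 and Jabba. These 3 lists passed camera at its preset correlation but not with an estimated correlation (adjusted p = 0.133, 0.306 and 0.0770). The 30 detoxification, lipid and chaperone genes picked for their rise after 1 exposure had a median log2 fold change of 0.06 from naive, with 6 of the 30 called higher. The muscle gene Prm, which encodes paramyosin, fell from 1401 ± 250.5 to 777 ± 89.6 and the adult cuticle protein gene Acp1 from 5776 ± 884 to 2768 ± 929 (n = 6 each). The highest folds were those of phu (2.85, 2.01 to 4.02), Lsd-1 (2.40, 2.08 to 2.77) and the lipid droplet gene Jabba (2.15, 1.90 to 2.43). In limma, 590 of 9317 probe sets passed, 231 higher and 359 lower, with 19 higher and 42 lower by over 1.5-fold. The count of higher calls fell to 144 without five-exposure replicate 3 and to 153 without five-exposure replicate 4. Naive replicate 4 stood apart from the other naive arrays, with lower Prm and Acp1, and without it 676 probe sets passed. Groups did not overlap for 341 probe sets (3.66%, where chance gives 0.216%).

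Higher after 5 exposures were also CG5966 (1.86-fold, 1.74-fold with a pseudocount and 2.75-fold with a lower floor, a call lost in 3 alternatives given below), CG31778 (1.80-fold, 1.48 to 2.18), the drosomycin-like gene Drsl5 (1.69-fold), CG8389 (1.69-fold, 1.57 to 1.82), GstE9 (1.68-fold, 1.41 to 2.00) and the larval serum protein gene Lsp2 (1.64-fold, 1.38 to 1.95). The lowest folds were those of CG8736 (0.256, 0.182 to 0.360) and CG5172 (0.259, with 3 five-exposure arrays at the floor, and 0.402 with a pseudocount), followed by CG7214 (0.450), CG13043 (0.452), Acp1 (0.461, 0.357 to 0.595), the chitin-binding gene Gasp (0.480), the phagocytic receptor gene NimC4 (0.488, also with 3 arrays at the floor) and CG7203 (0.493). Vajk2 fell on each of 3 probe sets, by 1.67 on the log2 scale on 1 of them and by 0.54 on the chosen one. Slh disagreed between probe sets, at 0.03 on the chosen one and -1.09 on the other.

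Of 20 muscle markers, 13 fell and none rose, the same counts as adjusted over the list alone. Prm was at 0.560-fold (0.480 to 0.653), the alpha-actinin gene Actn at 0.624-fold (0.547 to 0.711), TpnC41C, a troponin C gene, at 0.727-fold, and up, the troponin T gene, at 0.637-fold on the chosen probe set, while its second probe set was not called (-0.04 log2, adjusted p = 0.758). The list adjusted p was 2.99e-12, with adjusted p = 0.133 with an estimated correlation. Of 46 cuticle protein genes 11 fell and none rose (16 lower adjusted over the list alone), among them Cpr97Eb (0.561-fold), Cpr100A (0.564-fold), Cpr97Ea (0.708-fold) and Cpr92F (0.728-fold), for a list adjusted p of 5.22e-07 and adjusted p = 0.306 with an estimated correlation. All 10 fatty acid oxidation genes had folds above 1 and 6 rose (9 adjusted over the list alone): the dehydrogenase gene scu (1.45-fold, 1.30 to 1.61), the thiolase gene yip2 (1.26-fold, 1.15 to 1.38), wal, which encodes an electron transfer flavoprotein subunit (1.17-fold), Echs1 (1.14-fold) and 2 others. That list had an adjusted p of 1.26e-08, and adjusted p = 0.0770 with an estimated correlation. In fatty acid synthesis and lipid storage 6 of 18 rose and 1 fell, with Lip4 at 1.32-fold, FASN1 at 1.29-fold and Acsl at 1.25-fold (7 higher and 3 lower adjusted over the list alone, list adjusted p = 0.0178, adjusted p = 0.534 with an estimated correlation). Its call was lost without naive replicate 5 (0.122) or five-exposure replicate 3 (0.0504) and with array weights (0.112).

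Of 21 glycolysis and trehalose genes 6 fell and 2 rose (12 and 3 adjusted over the list alone), with Glyp (0.765-fold), fbp (0.792-fold), Glys (0.827-fold) and Pglym78 (0.859-fold). The list adjusted p was 5.41e-05, and adjusted p = 0.273 with an estimated correlation. In alcohol and aldehyde metabolism the sorbitol dehydrogenase gene Sodh1 fell to 0.553-fold (0.461 to 0.663), the malic enzyme gene Men-b to 0.795-fold and ry, the xanthine dehydrogenase gene, to 0.797-fold, while Fdh rose 1.29-fold (1 higher and 8 lower of 14 adjusted over the list alone, list adjusted p = 0.00115, adjusted p = 0.365 with an estimated correlation). The neurotransmitter list was lower again with the same 4 genes called, Pu (0.684-fold, 0.605 to 0.772), ple (0.709-fold, 0.629 to 0.800), speck (0.752-fold) and Gat (0.795-fold), 5 lower adjusted over the list alone, at an adjusted p of 5.41e-05, and adjusted p = 0.0770 with an estimated correlation. Oxidative phosphorylation had 4 of 47 genes lower and none higher, with Cyt-c1 at 0.876-fold and a list median of -0.09 log2 (5 lower adjusted over the list alone, adjusted p = 4.75e-08, adjusted p = 0.534 with an estimated correlation). Mal-B2 (1.25-fold), sug (1.18-fold) and Mal-A5 (1.15-fold) rose among 12 genes of the maltase list (3 higher adjusted over the list alone, adjusted p = 0.0178, adjusted p = 0.306 with an estimated correlation), whose call was lost without naive replicate 5 (0.0594) or 6 (0.0566).

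Small shifts passed for 3 further lists. All 27 ribosomal protein genes had folds above 1 with none called (median 0.04 log2, adjusted p = 0.0178, adjusted p = 0.858 with an estimated correlation), 4 of 27 proteasome genes had folds above 1 with none called (adjusted p = 0.0178, adjusted p = 0.712 with an estimated correlation), and of 11 glia markers wun2 fell to 0.834-fold and none rose (3 lower adjusted over the list alone, adjusted p = 0.0381, adjusted p = 0.306 with an estimated correlation). By limma, 2 ribosomal and 2 proteasome genes had an unadjusted p under 0.05. The ribosomal call was lost without naive replicate 3 (0.0593) or 5 (0.0648), and the proteasome call without naive replicate 3 (0.0768), 4 (0.0600) or 5 (0.0648), five-exposure replicate 2 (0.0670) or with array weights (0.0935). The glia call was lost without naive replicate 2 (0.0837), 3 (0.0596), 4 (0.0606) or 6 (0.0566), five-exposure replicate 2 (0.0696), 3 (0.0534), 4 (0.0549) or 6 (0.0536), and with a stricter filter on low values (0.0929). Outside called lists, the neuropeptide gene CCHa2 rose 1.40-fold and Nplp3 fell to 0.780-fold, the activity-regulated gene Arc1 rose 1.27-fold, and the photoreceptor channel gene trpl fell to 0.852-fold. The clock list did not pass (adjusted p = 0.939), and hang and slo were not called. Without a filter on low values the calls of CG5966 (adjusted p = 0.0802), Glyp (0.0691), Mal-A5 (0.0612), sug (0.0601) and FASN1 (0.0544) were lost, and that of CG5966 also with a trended and robust prior (0.0507). Without the least correlated arrays they were lost for Mal-A5 (0.140), CG5966 (0.0827), Glyp (0.0665) and Cyt-c1 (0.0514), and with only the 2 groups compared for Cyt-c1 (0.0649) and Mal-A5 (0.0556). Under quantile normalization the calls of trpl (adjusted p = 0.0517) and Cyt-c1 (0.0684) were lost. Calls were lost without any of 6 arrays for Mal-A5 (adjusted p up to 0.0773), 5 for Cyt-c1 (0.0797) and sug (0.0677), and 3 for Echs1 (0.0618). Lists not called had adjusted p from 0.0983 to 0.966. Of the splits of these 12 arrays, 15 of 100, the real one included, gave at least the 12 lists called. The 18S rRNA ratio was -2.13 ± 0.60 in five-exposure arrays against -2.92 ± 0.44 in naive ones (n = 6 each, exact permutation p = 0.0325, adjusted p = 0.195).

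**Figure D2:**
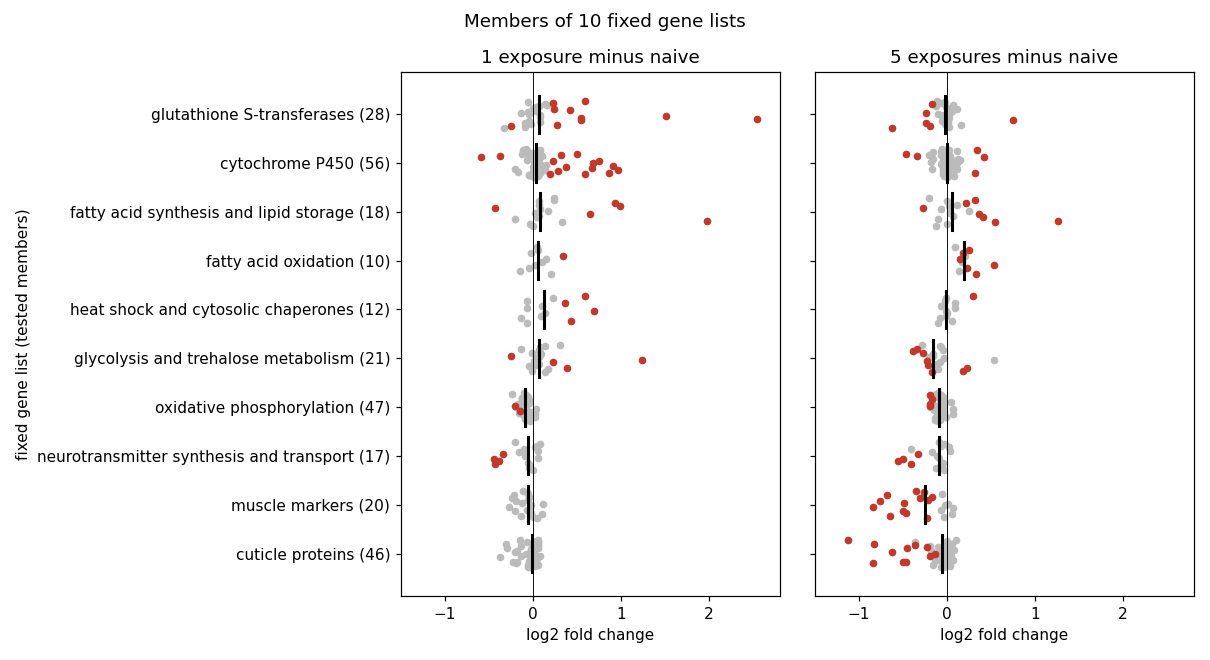
Log2 fold changes (horizontal axis) of the tested members of 10 fixed gene lists (number of members in parentheses), 1 exposure minus naive on the left and 5 exposures minus naive on the right. Red points passed an adjusted p of 0.05, grey points did not, and black bars are list medians, which for muscle markers were -0.06 after 1 exposure and -0.24 after 5 exposures.

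The third comparison asks how heads after 5 exposures differed from heads after 1. Lower after 5 exposures than after 1 were 13 of 21 glycolysis and trehalose genes, 8 of 20 muscle markers, 7 of 28 glutathione S-transferases, 4 of 12 chaperones and 9 of 46 cuticle protein genes, while 3 of 10 fatty acid oxidation genes, phu and fit were higher. None of the 9 lists called by camera at its preset correlation passed with an estimated correlation (adjusted p = 0.0594 to 0.579). GstE7 was lower at a fitted 0.171-fold, with 4 of the 6 five-exposure arrays at the floor (0.281-fold with a pseudocount and 0.160-fold with a lower floor). GstE3 stood at 0.336-fold (0.282 to 0.399) and Nmdmc at 0.321-fold (0.279 to 0.370), while phu was 6.48-fold higher (4.58 to 9.16) and fit 2.73-fold (2.18 to 3.41). In limma, 792 of 9317 probe sets passed, 348 higher (43.9%, but 48.7% under median centring and 53.6% under quantile normalization) and 444 lower, and groups did not overlap for 475 (5.10%, where chance gives 0.216%).

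After 5 exposures, CG8736 (0.337-fold), CG6908 (0.347-fold), Ugt37A3 (0.424-fold), CG5172 (0.486-fold, with 3 five-exposure arrays at the floor), Acp1 (0.511-fold) and Cyp309a1 (0.512-fold) were also lower than after 1. Higher were Cyp4ac1 (2.03-fold, 1.75 to 2.35), CG13315 (1.90-fold), CG17124 (1.81-fold), CG8389 (1.79-fold, 1.66 to 1.93), CG5618 (1.78-fold), CG8745 (1.76-fold), CG8665 (1.75-fold) and CG13607 (1.73-fold). Of 28 glutathione S-transferases 7 were lower and none higher, with GstD1 at 0.614-fold and GstE6 at 0.699-fold (10 lower adjusted over the list alone, list adjusted p = 1.2e-06, adjusted p = 0.0594 with an estimated correlation). P450 genes went both ways, 11 of 56 lower and 5 higher, with Cyp6d5 (0.512-fold) and Cyp6a2 (0.530-fold) among the lower (16 lower and 5 higher adjusted over the list alone, list adjusted p = 0.00888, adjusted p = 0.490 with an estimated correlation, and 0.145 without a filter on low values, which ends the call). Glycolysis and trehalose genes had 13 of 21 lower and 1 higher (17 and 1 adjusted over the list alone), including AGBE (0.664-fold), UGP (0.815-fold), Pglym78 (0.840-fold) and Ald1 (0.867-fold), at an adjusted p of 3.3e-09, and adjusted p = 0.0594 with an estimated correlation. Gapdh1 was not called in either comparison with naive heads.

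Hsp26 (0.617-fold), Stip1 (0.771-fold), DnaJ-1 (0.817-fold) and Hsc70-4 (0.828-fold), the 4 chaperone genes that rose after 1 exposure, were lower after 5 exposures than after 1 (6 lower of 12 adjusted over the list alone, list adjusted p = 0.0172, adjusted p = 0.490 with an estimated correlation). Both comparisons use the same single-exposure arrays, so part of this follows from picking genes high there. DnaJ-1 was still called above naive heads after 5 exposures (log2 fold change 0.3, limma adjusted p = 0.0389), a call lost without any of 8 arrays (up to 0.107). Without single-exposure replicate 3 the log2 fold change of Hsp26 moved from -0.70 to -0.45 and that of Stip1 from -0.38 to -0.24, both still called, while DnaJ-1 lost its call (adjusted p = 0.0544), and under quantile normalization the call of Hsc70-4 was lost (adjusted p = 0.0806). Men (0.515-fold, 0.470 to 0.564), AcCoAS (0.670-fold) and Sodh1 (0.632-fold) were lower in the alcohol and aldehyde list (7 lower and 2 higher of 14 adjusted over the list alone, adjusted p = 0.00626, adjusted p = 0.490 with an estimated correlation), and ATPCL (0.512-fold) and Agpat2 (0.609-fold) in the lipid synthesis list, which did not pass (adjusted p = 0.105). In muscle 8 of 20 genes were lower and in cuticle 9 of 46 (12 and 9 adjusted over the list alone, list adjusted p = 2.51e-06 and 0.00160, adjusted p = 0.490 and 0.579 with an estimated correlation). Fatty acid oxidation had scu (1.42-fold), wal (1.21-fold) and Echs1 (1.15-fold) higher of 10 (5 adjusted over the list alone, adjusted p = 0.000520, adjusted p = 0.490 with an estimated correlation). The immune list moved up, with Drsl5 (1.56-fold), PGRP-SB1 (1.54-fold) and GNBP3 (1.27-fold) higher and pirk (0.772-fold) lower of 20 (3 and 1 adjusted over the list alone, adjusted p = 0.0397, adjusted p = 0.490 with an estimated correlation). Its call was lost without single-exposure replicate 2 (0.0715), 3 (0.0502) or 4 (0.0641), five-exposure replicate 3 (0.0678), the filter (0.0680) or with a stricter filter on low values (0.0791). Among clock genes, Usp8 was lower (0.544-fold) and Clk higher (1.27-fold), and vri was lower (0.804-fold). Calls were lost without any of 6 arrays for Stip1 (adjusted p up to 0.0834) and DnaJ-1 (0.0829), and without a filter on low values for Stip1 (0.105), DnaJ-1 (0.0969) and Hsp26 (0.0675). With only the 2 groups compared they were lost for Stip1 (0.0715) and DnaJ-1 (0.0643), and without the least correlated arrays for Stip1 (0.0721), GNBP3 (0.0606) and DnaJ-1 (0.0535). At least the 9 lists called here were also called in 24 of 100 splits, the real one included. Lists not called had adjusted p from 0.0755 to 0.979.

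The comparisons with naive heads shared the 6 naive arrays. Of the 412 and 590 calls, 114 probe sets were in both, 98 in the same direction (58 higher and 40 lower) and 16 in opposite directions. Lsd-1 and Jabba (1.71-fold after 1 exposure) were higher in both, and CG6330 lower in both (0.822-fold after 1 exposure). Independent lists of these sizes would share 12.6 in the same direction. When the naive arrays were split 3 and 3 between the comparisons in 20 arrangements, 28 to 47 probe sets were shared, from fewer calls per comparison (means of 266 and 363). The correlation of log2 fold changes across probe sets, which are not independent replicates, was 0.365, against 0.503 for simulated unchanged groups. The covariance was 0.00574 observed and 0.0019 simulated, a difference of 0.00384. The simulated noise was independent between probe sets. With the naive arrays split, the correlation was 0.0698 to 0.348 (mean 0.193) and the covariance 0.00139 to 0.00548 (mean 0.0034). The sign was the same for 65% of probe sets, against 66.8% simulated and a mean of 53% with the split.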

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

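The tests on normalization, array order, tissue share, elapsed time and clock genes were chosen after the results were seen, while the splits of the arrays were not. For the tests with control ratios as covariates the bound was set beforehand, but the genes were those called in the comparison. Their covariates were the 18S rRNA and actin ratios, without those of GAPDH and eIF-4a. Chance was an unlikely source of the counts of genes in each comparison. Of 100 splits of the 12 arrays, the real one and others drawn at random, only the real one gave as many calls. These were 412 against at most 282 otherwise for 1 exposure against naive, 590 against 429 for 5 exposures against naive, and 792 against 90 for 5 exposures against 1. The splits do not address array order or batch, which go with the group. Chance stayed a possible source of the counts of lists, where 11, 15 and 24 of 100 splits gave as many, with 10 against up to 18, 12 against up to 17, and 9 against up to 15. For the 98 probe sets shared in direction, 1 of 100 regroupings of the 18 arrays, the real one, gave as many, and the highest of the others was 0. Groupings with few calls can share few, so this argues against chance no further than the counts of genes do.

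Probe sets called in opposite directions after 1 and after 5 exposures numbered 16. The difference between 1 and 5 exposures passed limma for each of them, which follows from how they were picked and adds no support. Named genes among them were Nmdmc, Shmt, aay, CG3609, Cyp309a1, CG16704, CG16713, CG33110 and Sidpn, higher after 1 exposure and lower after 5, and phu, Cyp4ac1, Acsf2 and Odc1, which went the other way. Some were chosen for naming after their values were seen. Several belong to this set only narrowly: leaving out 1 array ended the call after 1 exposure for Odc1 (any of 12 arrays, adjusted p up to 0.127), and the call after 5 exposures for CG16713 (9 arrays, 0.0919), CG3609 (7, 0.0707), Acsf2 (5, 0.0786) and Odc1 (5, 0.0768). Without a filter on low values these calls were lost as well (adjusted p = 0.0525 to 0.0975), as was that of CG16713 after 1 exposure (0.0507), and without the least correlated arrays those of Odc1 (0.119 and 0.0512) and of CG16713 after 5 exposures (0.0778). In data outside the gene measurements, the 18S rRNA control ratio had a mean of -1.99 in single-exposure arrays against -2.92 in naive ones, without overlap (exact permutation p = 0.00216, the smallest possible, adjusted p = 0.0518). The actin ratio was 2.18 ± 0.12 and 2.21 ± 0.15 after 1 and 5 exposures against 2.01 ± 0.08 (n = 6 each, exact permutation p = 0.0152 and 0.0216, adjusted p = 0.173 for both). The GAPDH and eIF-4a ratios showed no such difference (exact permutation p from 0.515 to 0.996). The mean GAPDH ratio was 1.3 in each group. That of eIF-4a was 0.54 in naive arrays, 0.57 after 1 exposure and 0.51 after 5.

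The first pattern is that 30 of 114 detoxification, lipid storage and chaperone genes were higher after 1 exposure (median log2 fold change 0.59). Of the 30, 29 or more stayed called under quantile normalization and median centring, which argues against a remaining difference in scale between arrays. Both scalings were applied to values that the authors had already normalized. They cannot undo that step, so an effect of the authors' normalization itself cannot be decided. With the 18S rRNA and actin ratios as covariates the median was 0.58 and 21 of 30 stayed called, while calls over all probe sets fell from 412 to 241. These values met the bound set beforehand against RNA quality, as read from these ratios, as the whole cause. But the 18S rRNA ratio did not overlap between naive and single-exposure arrays. The fit therefore cannot separate that ratio from the group, and the question stays open. The order in which arrays were numbered cannot be told apart from the groups, because the group changed 2 times along the 18 array numbers. A response to ethanol may account for the pattern, and was not separated from array order or RNA quality.

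The second pattern is that 24 muscle and cuticle genes were lower after 5 exposures (median log2 fold change -0.46). A lower share of muscle or of cuticle-forming tissue cannot be told apart from a change within the tissue: 15 of 17 muscle and 19 of 24 cuticle members above an intensity of 200 changed relative to the mean of these members (limma, adjusted p under 0.05), but such ratios go both ways by construction and unequal falls also follow from expression in other tissues. With the 18S rRNA and actin ratios as covariates the median moved only to -0.41. However, 12 of the 24 lost their call, the most that the bound set beforehand allowed, as calls over all probe sets fell from 590 to 217. The 18S rRNA ratio overlapped between these groups only through five-exposure replicate 2 (-3.286). The test thus argues only weakly against RNA quality, as read from these ratios, as the whole cause of the fall. Time and age passing during 5 exposures cannot be told apart from ethanol without an air-only group of that duration, and these genes also lay -0.31 from single-exposure heads in the median. An effect of repeated ethanol stays open as well. Prm and Acp1 also varied without ethanol, as naive replicate 4 was low for both (938.3 and 4156). It still lay above each five-exposure array (at most 884.3 and 3853.8).

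The third pattern is the change in clock transcripts after 1 exposure. Of 7 rhythmic transcripts, 6 moved in the direction assigned to a later time of day (per, tim, vri, Pdp1 and cwo higher, Clk and cry lower). Of the 6, 3 were called (tim, vri and Clk, of which tim was not called without a filter on low values, limma adjusted p = 0.0644). The other 1, cwo, moved against its assigned direction and was called. The assigned directions hold only for part of the day, so the match does not show that collection was later. A later time of day at collection after 1 exposure may account for part of it and cannot be told apart from ethanol, because collection times are not given in the sources used here.

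Single arrays lay far from the other 5 of their group in 31 of 417 groups of 6 values over 139 genes, where chance gives about 1 in 20, judged by the gap to the nearest array as a share of the group's range. Naive replicate 4 held 12 of them. It was low for Gat (0.773), Nplp3 (0.754), Actn (0.727), Gasp (0.721), CG7214 (0.712), Acp1 (0.661) and Prm (0.653), and high for GstE7 (1, the other 5 arrays being at the floor), CG5966 (0.930), Lip4 (0.797), Jabba (0.785) and Drsl5 (0.694). Single-exposure replicate 3 was high for Hsp26 (0.889), Ostgamma (0.729), Hsc70-4 (0.708), Gart (0.690) and Stip1 (0.648). Five-exposure replicate 5 was low for Sec61gamma (0.761), Srg1 (0.737) and Sec61alpha (0.643). Others were Usp8 (0.768) and ana (0.719) high in naive replicate 2, CG3609 (0.737) and scu (0.629) low in naive replicate 6, aay (0.675) low in naive replicate 1, and Cyp4ac1 (0.726) low in naive replicate 5. CG31778 (0.751) was low in single-exposure replicate 2, CG33110 (0.679) low and ND-B14 (0.708) high in single-exposure replicate 1, GstE7 (0.677) high in five-exposure replicate 3, where 4 of the other arrays lay at the floor, and Gasp (0.635) high in five-exposure replicate 1.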

How the results depend on the processing

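The alternative without the least correlated array of each group was chosen after seeing the data. Total counts of genes, lists and shared probe sets stayed within 1.5 times in all alternatives run, from 329 to 507 genes after 1 exposure, 431 to 769 after 5, and 607 to 898 between them. Counts by direction moved more. Higher calls after 5 exposures fell from 231 to 144 without five-exposure replicate 3 and to 153 without replicate 4. Lists higher after 5 exposures fell from 4 to 1 without naive replicate 5 and to 2 without the least correlated arrays. In 5 against 1 they moved from 2 to 4 under quantile normalization and to 1 with a stricter filter, without the least correlated arrays, or without single-exposure replicate 2 or 4 or five-exposure replicate 3. The share of genes higher moved from 58% to 51.1% under quantile normalization, 50.6% under median centring and 49.6% without naive replicate 5 after 1 exposure, and from 43.9% to 53.6% under quantile normalization in 5 against 1. Of 274 gene results called, 223 were called under each of 29 alternatives, 51 lost the call under at least 1, and 0 reversed. Of 143 not called, 33 passed under at least 1. Lists that passed only under alternatives numbered 13, among them glia in 11 and maltases in 7 alternatives after 1 exposure, and in 5 against 1 ribosomal genes in 9 and oxidative phosphorylation in 1 (adjusted p = 5.98e-05). Fry called 11 lists after 1 exposure, 10 after 5 and 12 in 5 against 1. It passed some that camera did not, such as histone acetylation after 1 exposure (fry adjusted p = 0.000484) and neuropeptides after 5 (0.0353). Oxidative phosphorylation, called by camera in both comparisons with naive heads, did not pass fry (0.0527 and 0.0827).

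List calls were lost as follows, and the cause was not tested. Without a filter on low values: antimicrobial genes after 1 exposure (adjusted p = 0.0986) and in 5 against 1 (0.0680), and P450 genes (0.129 and 0.145). With a stricter filter: glia after 5 (0.0929) and antimicrobial genes in 5 against 1 (0.0791). With array weights: lipid synthesis (0.112) and proteasome (0.0935) after 5. Without the least correlated arrays: antimicrobial genes (0.0908) and muscle (0.0565) after 1, ribosomal genes (0.119) and lipid synthesis (0.128) after 5, and antimicrobial (0.0628), cuticle (0.0657) and P450 genes (0.0526) in 5 against 1. With each array left out in turn, adjusted p ranged after 1 exposure from 0.00313 to 0.0637 (antimicrobial), 0.00335 to 0.0988 (glycolysis) and 7.97e-06 to 0.0990 (muscle). After 5 they ranged from 0.000909 to 0.0648 (ribosomal), 0.00723 to 0.122 (lipid synthesis), 0.0124 to 0.0837 (glia), 0.0101 to 0.0594 (maltases) and 0.00106 to 0.0768 (proteasome), and in 5 against 1 from 0.0064 to 0.0715 (antimicrobial). A replicate block gave 502, 683 and 898 genes, without the calls of Odc1 after 1 exposure (adjusted p = 0.0578) and of Mal-A5 (0.0529) and Srg1 (0.0626) after 5. For naive and single-exposure arrays 2 of 6 correlated best with the array of their own number, for naive and five-exposure arrays 1 of 6, and for single-exposure and five-exposure arrays 4 of 6 (0.255 to 0.52, with numbers 1 and 3 at -0.054 and 0.079), a hint of shared conditions from the data and not from the labels. As not every number correlated over 0.1, the numbers were not read as pairs. With a pseudocount in place of the floor the folds of weak signals were smaller, as for GstE7 after 1 exposure (3.73 against 5.85) and CG5172 after 5 (0.402 against 0.259), and a lower floor gave larger ones, as for GstE7 (6.96) and CG5966 (3.99 against 2.69) after 1 exposure. Signal near the floor limits folds for the 12 probe sets with arrays there, but not for these alone. The log2 fold change of phu in 5 against 1 was 2.29 with a pseudocount against 2.70, although its lowest array (106.8) lay above the floor. Those of Ugt37A3 (0.83 against 1.13) and Usp8 (0.62 against 0.88) after 1 exposure were smaller with a pseudocount as well.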

Other observations

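The genes of this part were gathered after their values were seen, so counts and single-gene results of limma are given and no test of a group. Of 17 tested genes of folate-dependent one-carbon metabolism and purine synthesis, 8 were lower after 5 exposures than in naive heads and none higher. Gart, an enzyme gene of purine synthesis, fell to 0.506-fold (95% interval 0.444 to 0.576), aay, a phosphoserine phosphatase gene, to 0.605-fold (0.564 to 0.649), Pfas to 0.676-fold and pug to 0.679-fold. After 1 exposure 5 of the 17 were higher and 1 lower. Both Nmdmc and Shmt, the serine hydroxymethyltransferase gene, were higher after 1 exposure and lower after 5, with Nmdmc at 2.17-fold and 0.699-fold and Shmt at 1.25-fold and 0.701-fold.

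Of 23 tested genes gathered for protein entry into the endoplasmic reticulum, 4 fell after 1 exposure and none rose, Tapdelta to 0.715-fold (0.647 to 0.790), Sec61alpha to 0.744-fold, Sec61gamma to 0.748-fold and Sec61beta to 0.803-fold. After 5 exposures 1 of the 23, Ostgamma, was called against naive, and it was higher, a call lost under median centring (adjusted p = 0.0605), without the least correlated arrays (0.0735) and without any of 8 arrays (up to 0.108). Compared with 1 exposure, 11 of 23 were higher after 5 exposures and none lower, Tapdelta by 1.48-fold and Sec61gamma by 1.45-fold. Of 15 amino acid breakdown genes, 6 were lower and none higher after 5 exposures, with Hpd at 0.600-fold and Oat at 0.705-fold, and after 1 exposure 3 were lower and 1 higher.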
